A study of Drosophila melanogaster with 3 samples.

How the data were processed

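The data were ChIP-seq peak lists of 3 biological replicates of 0 to 24 h whole embryos of a Drosophila line expressing a C-terminal GFP fusion of Su(H). Per the labels, the antibody was directed at GFP, although one label field names Su(H) itself, and chromatin was sheared by sonication to 200 to 800 bp. Replicate numbers were those in the labels. As all libraries came from 1 group, no contrast between groups was made.

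Per the lists of files deposited with the series, each replicate list was made from the alignments of 1 library and a control file. A pooled list was made from the alignments of all 3 libraries and a control file. The thresholded list came from the pooled list and the 3 replicate lists by irreproducible discovery rate (IDR). This method rests on the agreement of peak ranks between replicates. The aligner, the peak caller and the IDR threshold are not given in the sources used here. The deposited signal value of each peak is the authors' own and is not stated to be scaled for depth, and the deposited −log10 q value was capped by ties at its maximum, reached by 3569 of the thresholded peaks. These values were used only to rank peaks and to describe them. The summit offset deposited by the authors gave the position of each summit. Lists existed for dm6 and dm3. All comparisons used dm6, and dm3 lists were compared by counts only. The replicate and pooled lists held exactly 30000 peaks each, so the number of peaks says nothing about a library, and they include background by design. Every thresholded summit was also a summit of the pooled list, and the thresholded peaks were the 3833 of highest pooled signal. Joining summits within 500 bp left 3670 regions. Median peak width was 416 bp in the pooled list, and 396, 420 and 396 bp in replicates 1 to 3. Read depth is unknown from the lists, so no interval for signal was derived from counts. Intervals for shares of peaks are 95% Wilson intervals and cover counting error only. Errors on signal are the SD over 3 replicate lists and include any difference in depth between them.

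Genes came from the Ensembl release 115 annotation (BDGP 6.54) of the dm6 assembly, and sequence from the same assembly. No peak reached beyond the end of its chromosome. A replicate peak matched a peak when their summits lay within 200 bp. For location and replicate agreement, all peaks of a chromosome were moved together by a random distance, 1000 times (circular shifts). A summit was at a promoter when within 500 bp of an annotated start, and was otherwise put in the first that applied of 5' untranslated region, coding exon, 3' untranslated region, other exon, intron or intergenic. A gene was counted as having a peak when a thresholded summit lay in it or within 2 kb. For each of 32 gene lists the count was compared with 10000 random lists of protein-coding genes matched in 20 bins of gene length (two-sided permutation test, smallest p 0.0002). Some members appear in more than 1 list, and 7 symbols were updated to their current names, Bob and BobA being counted as 1 gene. For 11 motifs, windows of 100 bp to each side of a summit were compared with windows centred 1 kb to both sides by Fisher's exact test, two-sided. Facing site pairs (YGTGDGAA, 14 to 18 bp apart) were sought within 200 bp of summits. The sequence and position of 1 pair are not reported here. The rank of peaks with and without a site was compared by 100000 permutations. P values were adjusted by the Benjamini-Hochberg method within location classes, lists, motifs and 8-mers. Neighbouring peaks and genes are not independent, which the length-matched and Fisher's exact tests leave out and the shifts keep. Spearman correlations used pairs of peaks that were each other's nearest summit.

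Genes, lists, motifs, tests and alternatives were fixed before the data were examined, except where stated. Named genes were those of the 20 strongest thresholded peaks (the gene holding the summit, otherwise the nearest start), all members of the E(spl) and Brd complexes, up to 4 members of each other list with the strongest peak, and Su(H) and w.

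On simulated data for Su(H) motif enrichment, sites planted in 4.77% of 3833 windows raised the share with a site by 4.7 percentage points. Without planted sites, 6 of 100 sets of shifted peaks passed p of 0.05 by Fisher's exact test. Shifted peaks lose the placement of the real peaks at promoters, so the error rate in that setting was not measured. A planted 8-mer came first by p, and 20 of 20 planted site pairs were found among 3833 windows. For gene lists drawn from 13968 genes, 9 of 200 random lists and 100 of 100 lists with 12 of 15 bound members passed. Their members were drawn from the whole genome, so the error rate for lists of adjacent genes was not measured. For replicate agreement, copying 80.9% of 3833 peaks with jitter gave 81.5% matched. For peak rank, raising the rank of marked peaks among 3833 by 30% gave a permutation p of 0.0005, and of 1916 peaks placed near starts 100% were classed as promoter. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

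Alternatives covered the matching of peaks, the promoter and gene windows, the background of the gene and motif tests, the site consensus, the 1000 strongest peaks and leaving out each replicate. Shifts numbered 100 in the alternatives of replicate agreement and 200 in those of location.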

Results

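Binding of the Drosophila melanogaster transcription factor Su(H) was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq). Su(H), or Suppressor of Hairless, is the DNA-binding protein through which the Notch receptor regulates its target genes. The material was whole embryos of both sexes, collected 0 to 24 h after egg laying, from a transgenic line carrying Su(H) fused to green fluorescent protein (GFP). Chromatin was pulled down with an antibody against GFP. All 3 libraries were biological replicates of this 1 group, so the design held no contrast between conditions. The questions it answers are where in the genome the fusion protein was found, near which genes, with which sequences, and how well the replicates matched. The deposited files were peak lists with the authors' signal value and summit for each peak. Each replicate list and the list from the pooled libraries held 30000 peaks. A list that the authors made from the pooled and replicate lists, called thresholded below, held 3833 peaks on the dm6 genome. These were the peaks of highest pooled signal, so a single member need not rank alike in the replicates. Read depth is unknown from these lists, and a control library was not analysed here. All positions are in dm6.

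The strongest signal lay in an intron of ush, which encodes a GATA cofactor acting in blood and dorsal tissues. This peak, at 2L 480820 to 481317, had a pooled signal of 2733. Its summit lay 4866 bp from the nearest start of ush, but 1398 bp from a start of cbt. The matching replicate peaks had a signal of 908 ± 73.4 (SD, n = 3) and ranked 2, 1 and 1 in replicates 1 to 3. The next peaks were at the promoter of CG14100 (3L 19590421 to 19590814, replicate signal 876 ± 70.1) and at the promoter of the UDP-galactose transporter gene Ugalt (X 2703674 to 2704094, 838 ± 88.1). Next came a px promoter (2R 22514091 to 22514520, 726 ± 67.9) and an intron of the kinase gene Lk6 (3R 11760864 to 11761257, 708 ± 92.9). Of the 20 strongest peaks, 13 were at promoters, 5 in introns and 2 between genes. The worst rank any of them took in a replicate list was 29. The other promoter peaks among them lay at PNPase, CG1888, Chro, larp, CenG1A, ph-p, Art3, mRpL41 and CG31145. A further one had CG4004 as its nearest protein-coding gene, whose own start was 5104 bp away. The remaining introns were those of CG11050, CG9663 and CG32772. The intergenic peaks had CG13323 (11908 bp) and tara (3160 bp) as their nearest protein-coding genes. None of these 20 peaks held a Su(H) consensus site within 100 bp of the summit. Over all thresholded peaks only 3.57% held one, so its absence does not set these 20 apart.

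**Figure D1:**
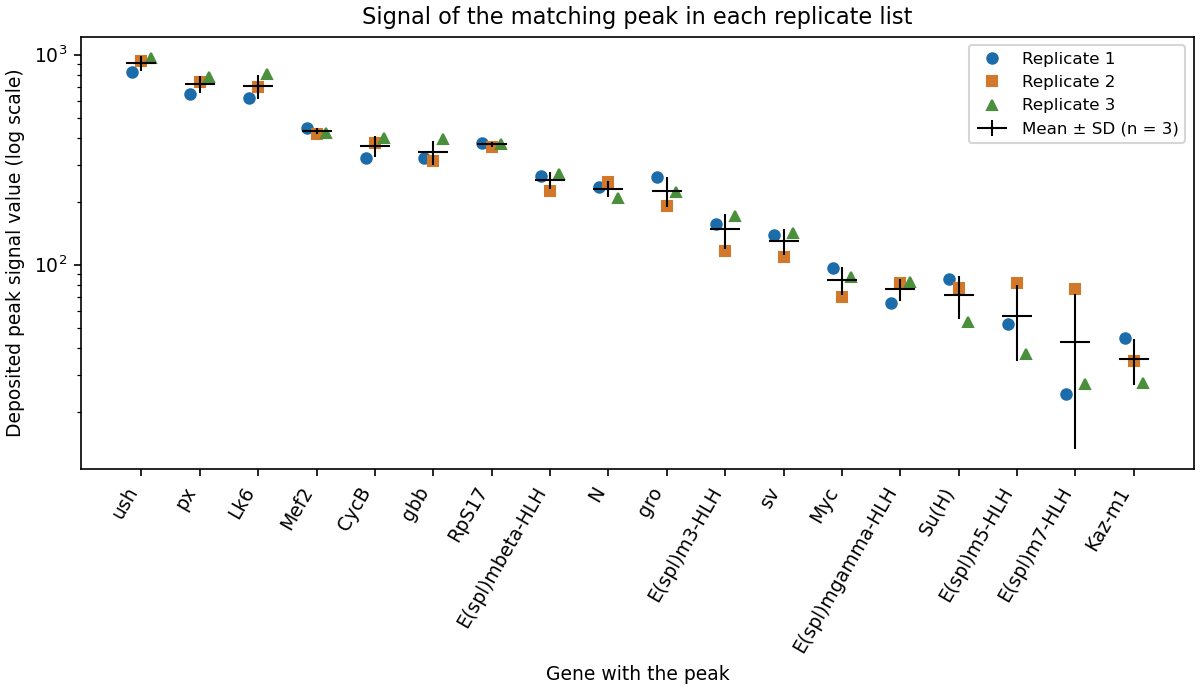
Deposited peak signal on a log scale (vertical axis) in the 3 replicate lists for the peak matched to each of 18 genes; points are single replicates, and horizontal and vertical black lines give the mean and the SD (n = 3). Signal ran from 908 ± 73.4 at ush to 35.7 ± 8.82 at Kaz-m1, where the nearest summit within 200 bp was used in each replicate.

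How far the replicates showed the same sites was asked first. Of the 3833 thresholded peaks, 3787 (98.8%) had a summit within 200 bp in replicate 1, 3816 (99.6%) in replicate 2 and 3814 (99.5%) in replicate 3. In all 3 replicates, 3751 (97.9%, 95% Wilson interval 97.4 to 98.3%) were found. Circular shifts of the peaks along their chromosomes gave 2.33% on average and 3.18% at most (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). Strong sites took similar ranks in replicates 1 to 3. Mef2, a regulator of muscle formation, ranked 16, 24 and 28, CycB, a mitotic cyclin, 38, 32 and 34, and the BMP ligand gene gbb 40, 48 and 35. Some weaker sites varied more. The peak at emc ranked 9866, 906 and 1712. When each replicate's own 3833 strongest peaks were compared, 68.4% of those of replicate 1 were in the set of replicate 2, 69.8% in that of replicate 3. Of those of replicate 2, 72.7% were in that of replicate 3. Across all matched peaks, Spearman's rho of the signal was 0.633 between replicates 1 and 2 (12250 peaks). It was 0.634 between 1 and 3 (12865 peaks) and 0.671 between 2 and 3 (13542 peaks). These are correlations across peaks, which are not independent replicates. The thresholded list had itself been made from the pooled and replicate lists of these libraries, so its match to them far above shifts was built in.

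Most thresholded peaks lay at promoters. Summits within 500 bp of an annotated transcription start made up 59.2% of the list (2269 peaks, 95% Wilson interval 57.6 to 60.7%), against 13.9% after circular shifts, a 4.25-fold excess. Introns held 28.1% (39.5% after shifts), and intergenic sequence 10.2% (26.4%). The 3' untranslated regions held 0.678% (4.54%) and coding exons 0.313%, 12 peaks, where shifts gave 14.04%. These 5 classes passed the two-sided permutation test (p = 0.002, the smallest that 1000 shifts can give, adjusted p = 0.0028). The 5' untranslated regions (0.548% against 0.796%, adjusted permutation p = 0.11) and other exons (0.939% against 0.828%, adjusted permutation p = 0.517) did not. Among the 500 strongest peaks the promoter share was 66.6%. By chromosome arm, 727 peaks were on 2L, 740 on 2R, 730 on 3L, 931 on 3R, 696 on X and 9 on chromosome 4.

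**Figure D2:**
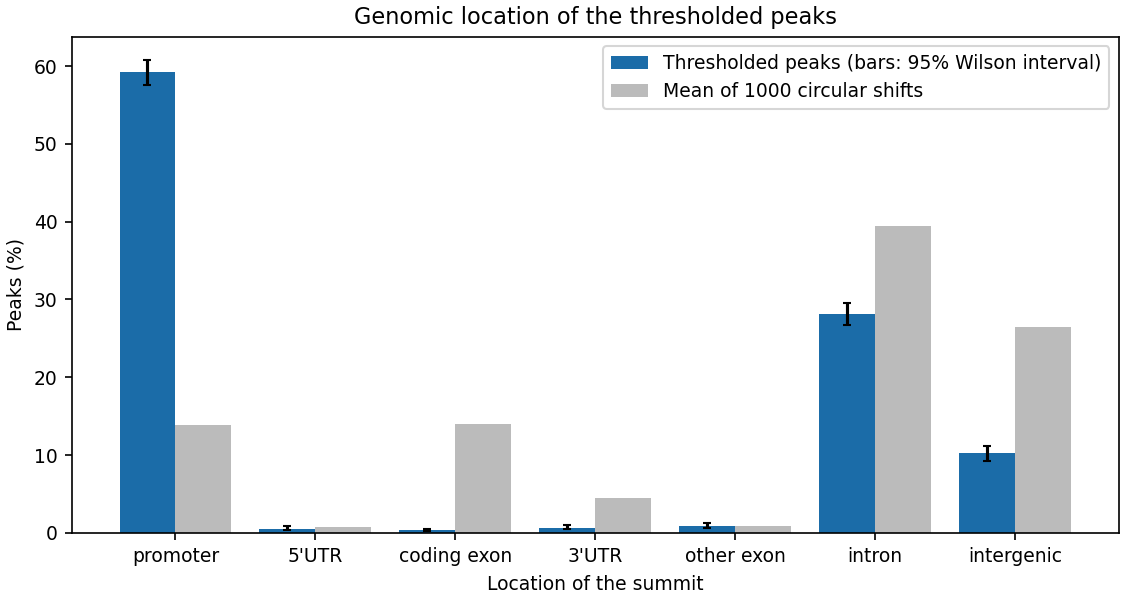
Share of the thresholded peaks (vertical axis, %) by location of the summit, with 95% Wilson intervals (blue), beside the mean of 1000 circular shifts (grey). Promoters took 59.2% of the peaks and 13.9% of shifted peaks, and coding exons 0.313% and 14.04%.

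The E(spl) complex, a cluster of basic helix-loop-helix repressor and Bearded-family genes that are the classical targets of Notch signalling, held more peaks than its gene lengths predicted. Of its 12 members 8 had a thresholded peak in the gene or within 2 kb, where length-matched lists had 2.55 on average (adjusted permutation p = 0.0064). The strongest was 294 bp from the start of E(spl)mbeta-HLH (3R 26006091 to 26006507), with a replicate signal of 253 ± 24.4 (n = 3) and a pooled rank of 76. The second strongest (3R 26042365 to 26042647, 224 ± 36.0, rank 104) was counted for E(spl)m8-HLH but lay 129 bp from a start of gro, the neighbouring corepressor gene. E(spl)m3-HLH had a peak 1046 bp upstream of its start (3R 26020599 to 26021136, 147 ± 27.9, rank 298), and a peak of rank 884 (3R 26041478 to 26041893) lay at the start of gro. There was an intergenic peak beyond E(spl)mgamma-HLH (3R 26002448 to 26002863, 76.6 ± 9.32, rank 1124). Other intergenic peaks lay near E(spl)malpha-BFM (65.0 ± 29.2, rank 1533), E(spl)m5-HLH (57.2 ± 22.6, rank 1936) and Kaz-m1 (35.7 ± 8.82, rank 3530). E(spl)m7-HLH had a promoter peak of 42.8 ± 29.6 (rank 2348), where a second summit of replicate 1 also lay within 200 bp and the nearer, weaker one was used. E(spl)m8-HLH also had a peak at its own promoter (3R 26039842 to 26040257, rank 2785). E(spl)mdelta-HLH, E(spl)m2-BFM, E(spl)m4-BFM and E(spl)m6-BFM had no thresholded peak, and their strongest pooled peaks ranked 10385, 5169, 15853 and 6551. With 5 kb on each side all 12 members had a peak (4.14 expected, adjusted permutation p = 0.0016). Counting only peaks within 1 kb of a start left 5 members (1.47 expected, adjusted permutation p = 0.112), and the 1000 strongest peaks left 3 (0.821 expected, adjusted permutation p = 0.303). Of 6849 runs of 12 adjacent genes elsewhere over 0.5 to 2 times the span, a comparison chosen after seeing the data, 14.5% had 8 or more genes with a peak (mean 4.37).

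**Figure D3:**
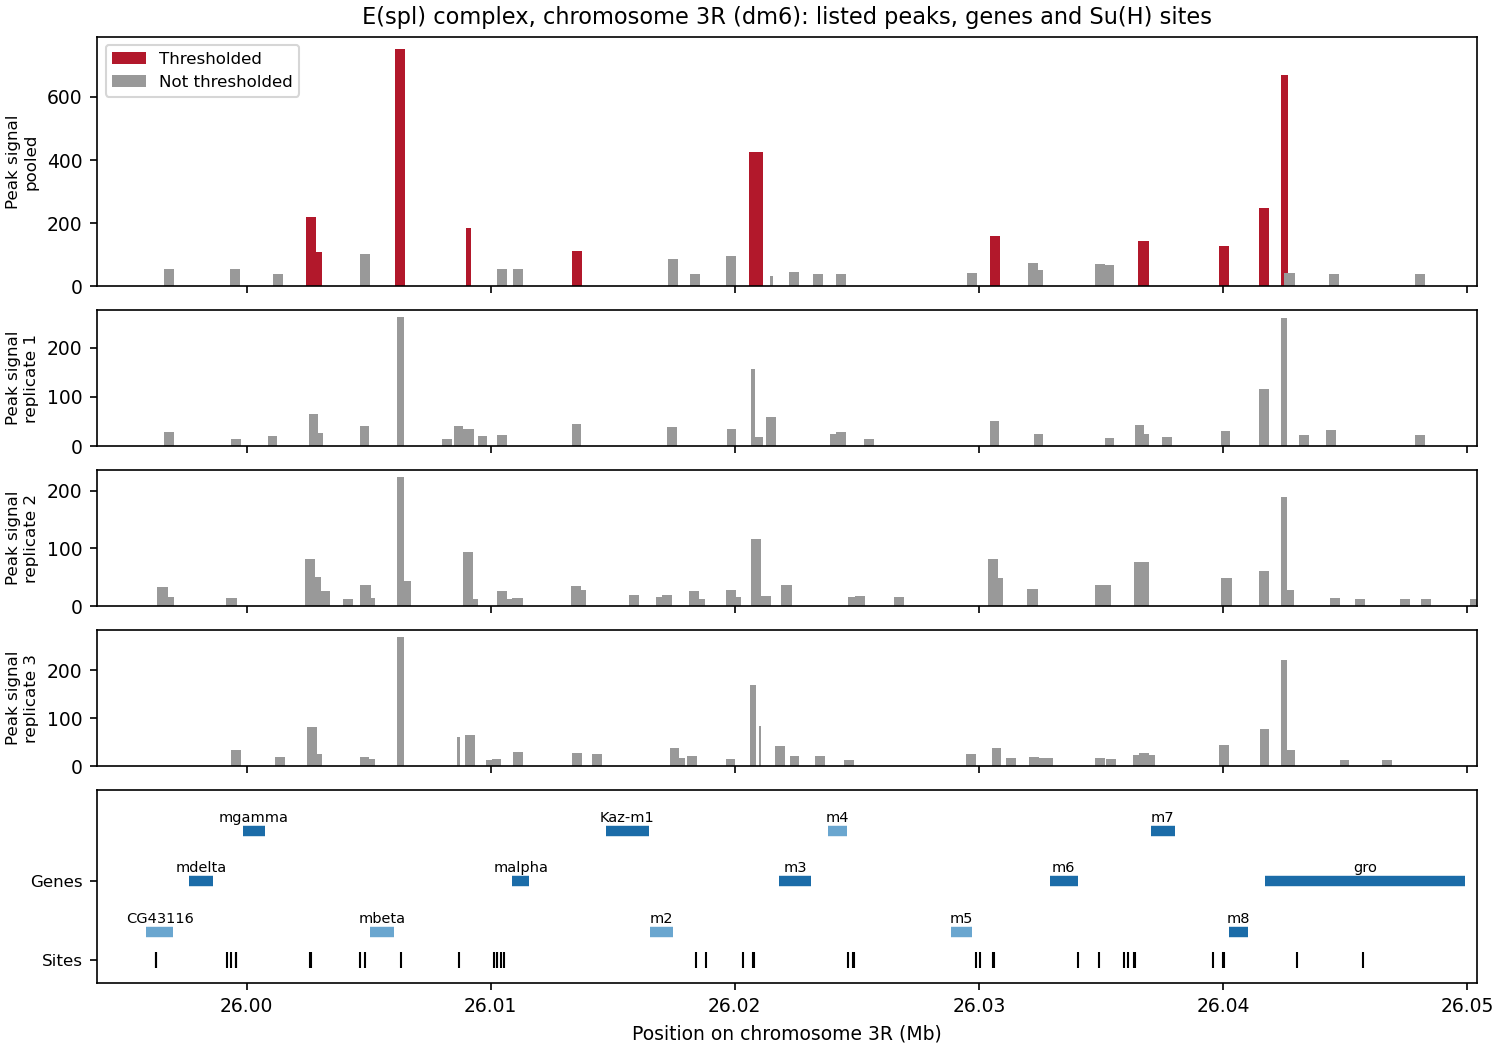
Listed peaks over the E(spl) complex on chromosome 3R (horizontal axis, Mb), drawn to scale with the deposited signal as bar height for the pooled list (red, thresholded; grey, not) and the 3 replicate lists; the bottom panel shows genes (dark, plus strand; light, minus strand) and matches to the Su(H) consensus. Of 33 pooled peaks in the region 12 were thresholded, and the highest stood at the promoters of E(spl)mbeta-HLH and gro.

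Genes that carry or tune the Notch signal were also occupied in part, without passing the test as a list. A peak was found at 16 of 25 pathway components, against 10.9 expected (adjusted permutation p = 0.195), and this count passed against shifted peaks (7.36 expected, adjusted permutation p = 0.0128). Shifts also remove the general placement of peaks at genes, so passing them does not set a list apart from other genes. The Notch receptor gene N had an intronic peak at X 3162254 to 3162729, 27652 bp from its nearest start, with a replicate signal of 230 ± 19.5 and a rank of 96. rumi, which encodes a glycosyltransferase acting on Notch, had a promoter peak of 141 ± 9.47 (rank 299), and aph-1, a subunit of gamma-secretase, one of 129 ± 12.2 (rank 382). Of 15 other known Notch targets 7 had a peak, against 7.04 expected (adjusted permutation p = 1.0): sv (129 ± 18.3, rank 363), Myc (84.8 ± 13.1, rank 757), edl (78.0 ± 4.46, rank 917), and ct (73.6 ± 18.2, rank 1018), with the other 3 at ranks 2615 to 3075. In the Brd complex, a second cluster of Bearded-family genes, 1 of 4 members had a peak, Ocho (39.7 ± 9.18, rank 3390), against 0.725 expected (adjusted permutation p = 1.0). The peak counted for Ocho lay 2844 bp from its own start, within 500 bp of the start of another gene. Su(H) and the eye-colour gene w had been named in advance because the line is transgenic. Su(H) itself had 2 thresholded peaks, the stronger at its promoter (2L 15039383 to 15039486, 72.0 ± 16.7, rank 1151). The gene w had none, its strongest pooled peak ranking 8729. Without a control library these values do not test the line.

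Outside the Notch lists, 3 lists had more peaks than expected. Ribosomal protein genes had peaks at 63 of 85 members (21.8 expected, adjusted permutation p = 0.0016), with promoter peaks at RpL7 (274 ± 64.0, rank 59), RpS27 (246 ± 55.5, rank 81) and RpL23A (199 ± 29.0, rank 128). Of 9 housekeeping genes 8 had a peak (3.02 expected, adjusted permutation p = 0.0064), among them Gapdh2 (180 ± 35.4), RpL32 (172 ± 24.0), Act5C (159 ± 18.2) and eEF2 (90.5 ± 11.3). All 10 ecdysone response genes, which encode the hormone's receptor and the nuclear receptors and other regulators it induces, had a peak (5.37 expected, adjusted permutation p = 0.0152), led by intronic peaks of Hr4 (174 ± 22.8), Hr3 (146 ± 15.1) and EcR (96.1 ± 4.13) and a promoter peak of Eip75B (145 ± 9.14). Within 1 kb of a start, 2 of the 10 ecdysone genes had a peak (3.33 expected, adjusted permutation p = 0.87), and 5 had one of the 1000 strongest peaks (2.24 expected, adjusted permutation p = 0.317). With 5 kb on each side the housekeeping list did not pass (8 of 9, 4.26 expected, adjusted permutation p = 0.0974).

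Peaks were scarce at 4 lists. None of the 15 gap and pair-rule genes, which pattern the early embryo, had a thresholded peak (5.34 expected, adjusted permutation p = 0.0119). This did not pass against shifted peaks (2.61 expected, adjusted permutation p = 0.307), within 1 kb of a start (adjusted permutation p = 0.13) or for the 1000 strongest peaks (adjusted permutation p = 0.542), and passed with 5 kb on each side (1 of 15, 7.3 expected, adjusted permutation p = 0.0064). Chemoreceptor genes, which serve smell and taste, had peaks at 10 of 179 members (54.9 expected, adjusted permutation p = 0.0016). Cuticle protein genes had them at 4 of 70 (18.2 expected, adjusted permutation p = 0.0016) and histone genes at 2 of 115 (16.1 expected, adjusted permutation p = 0.0016). The 2 histone genes were His2Av (89.3 ± 22.1) and His4r (62.2 ± 10.1). Most other members of that list are near-identical copies in an array, where reads are hard to place. Shifted peaks gave adjusted permutation p = 0.612 for histone and 0.324 for cuticle genes, and the 1000 strongest peaks gave 0.221 and 0.138. The peaks counted for Or85f (197 ± 33.5) and Ir68b (173 ± 32.6) lay 3128 and 2227 bp from those genes' own starts, within 500 bp of the start of another gene.

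The remaining 21 lists did not pass the test against length-matched lists, with adjusted permutation p from 0.0818 to 1.0. BMP pathway genes came closest, with 9 of 11 (4.88 expected), including gbb (343 ± 45.7), Med (227 ± 15.7), Mad (164 ± 25.5) and Dad (125 ± 11.5). EGFR pathway genes had 10 of 13 (6.52 expected), among them spi (191 ± 38.9), aos (171 ± 23.1) and S (156 ± 15.8). Cell cycle genes had 8 of 12 (4.56), led by CycB (368 ± 41.0). These 3 lists passed against shifted peaks (adjusted permutation p of 0.0213, 0.0274 and 0.0128), which again does not set them apart from other genes. The CycB peak was intergenic, 3337 bp from its start, and those counted for Med and gbb lay 5113 and 1168 bp from theirs, within 500 bp of the start of another gene. Ventral midline genes had 8 of 11 (5.43 expected), glial genes 6 of 9 (3.99), and salivary gland genes 3 of 5 (1.94). Heat shock genes had 8 of 19 (6.07), dorsoventral patterning genes 8 of 15 (6.32), Hedgehog pathway genes 4 of 8 (3.59) and gut and endoderm genes 4 of 9 (3.92). Counts at or below the expected ones were found for epidermis genes (5 of 10, 5.08 expected), segment polarity genes (5 of 11, 5.34), Wnt pathway genes (6 of 13, 6.73), and proneural and sensory organ precursor genes (5 of 16, 5.63). The same held for mesoderm regulators (7 of 19, 8.45), germline genes (2 of 7, 2.57), muscle structural genes (5 of 15, 6.56), hemocyte genes (5 of 15, 6.78), tracheal genes (3 of 9, 4.22), Hox genes (3 of 8, 4.34) and neuroblast and CNS patterning genes (5 of 21, 9.28). Single members of these lists carried strong peaks all the same, such as Mef2 (432 ± 14.8, rank 22), the glial gene moody (256 ± 34.7, rank 77), brat (187 ± 27.4, rank 152) and fz (160 ± 42.9, rank 225). Over the whole genome 4608 of 13968 protein-coding genes (33.0%) had a thresholded peak in the gene or within 2 kb.

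**Figure D4:**
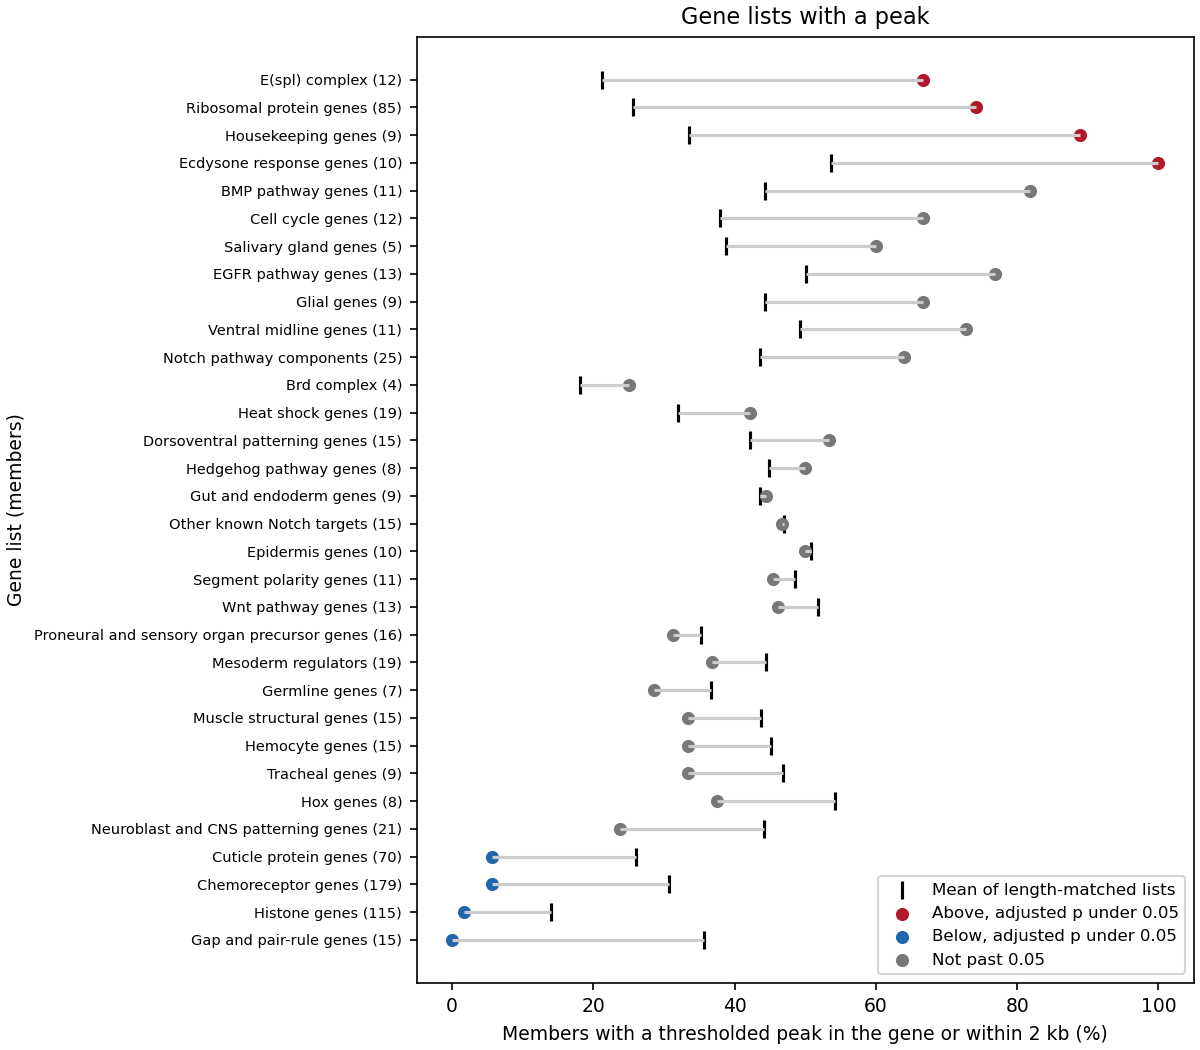
Share of each gene list's members with a thresholded peak in the gene or within 2 kb (horizontal axis, %; dots), beside the mean of 10000 length-matched random lists (vertical marks), with the number of members in brackets. Red dots are the 4 lists above and blue dots the 4 lists below the length-matched lists at an adjusted p under 0.05, and the E(spl) complex stood at 8 of 12 members.

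The sequence that Su(H) is known to bind, YGTGRGAA, was present within 100 bp of 137 thresholded summits (3.57%, 95% Wilson interval 3.03 to 4.21%) and in 2.17% of the windows 1 kb to either side, a ratio of 1.65 (Fisher's exact test, two-sided, adjusted p = 3.89e-05). The same letters in reverse order, as a control, stood at 1.88% and 1.73% (Fisher's exact test, adjusted p = 0.661). The DREF element TATCGATA was at 5.37% of summits and 0.574% of flanks, 9.36-fold (Fisher's exact test, adjusted p = 1.21e-57). Motif 1, the site of M1BP, was at 2.95% and 0.43%, 6.85-fold (Fisher's exact test, adjusted p = 3.24e-27). GAGA repeats were 1.42-fold more frequent at summits (Fisher's exact test, adjusted p = 0.000152). The proneural E-box (0.69-fold, Fisher's exact test, adjusted p = 1.21e-06) and the Runx site (0.826-fold, Fisher's exact test, adjusted p = 0.0104) were rarer there. The Zelda site (1.02% against 1.42%), the Twist/Snail E-box (7.96% against 9.09%), the Grainyhead site (0.235% against 0.339%) and the Pol III B box (0.0783% against 0.0522%) did not pass, with adjusted Fisher's exact p from 0.066 to 0.693. Against random positions of the same location class, a control chosen for these motifs after seeing the data, DREF was 4.53-fold enriched (1.19% of control positions) and the Runx site did not pass (0.865-fold, Fisher's exact test, adjusted p = 0.0708).

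The rank of peaks with a Su(H) site was not found to differ from that of other peaks. The median rank of the peaks with a site minus that of the others was 20.5 places (two-sided permutation p = 0.907). A site was found in 2.8% of the 500 strongest peaks and in 4.2% of the 333 weakest. The 10 strongest thresholded peaks with a site, a set chosen after the values were seen, included promoter peaks at CG3009 (rank 46), E(spl)mbeta-HLH (rank 76), Rgl (rank 86) and Asph (rank 112).

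**Figure D5:**
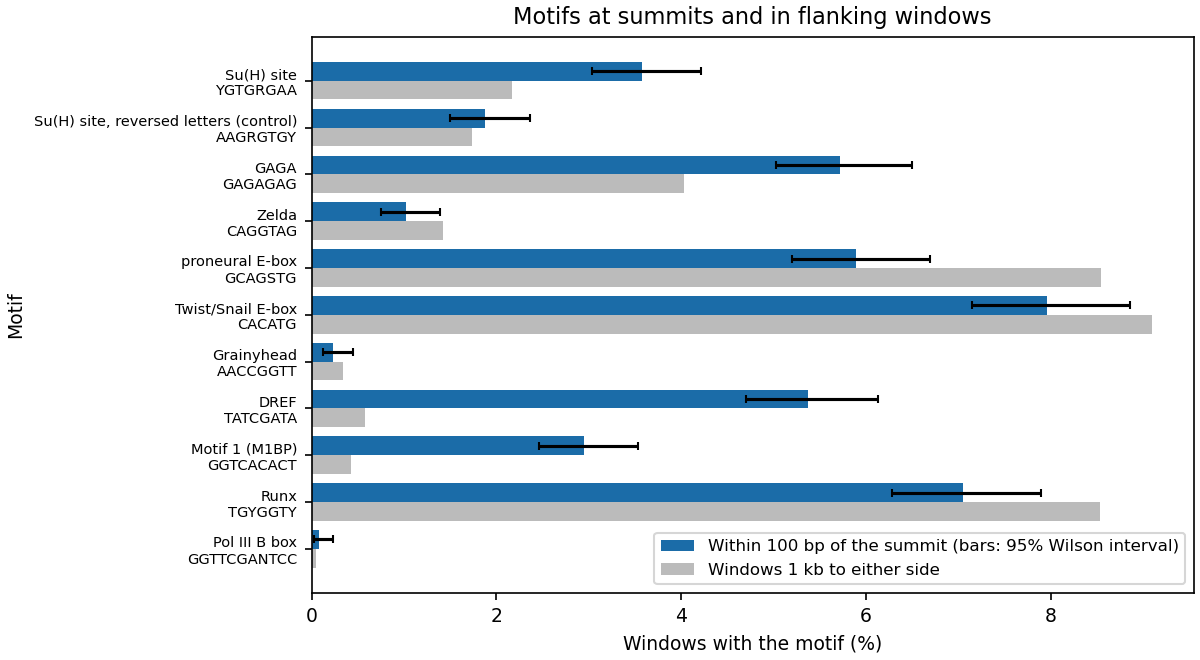
Share of windows with each of 11 motifs (horizontal axis, %) within 100 bp of the thresholded summits, with 95% Wilson intervals (blue), and in windows 1 kb to either side (grey). The Su(H) site stood at 3.57% and 2.17%, DREF at 5.37% and 0.574%.

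Facing pairs of Su(H) sites with 14 to 18 bp between them, the arrangement known from E(spl) enhancers, were found within 200 bp of 3 thresholded summits and in none of 7666 flanking windows (Fisher's exact test, two-sided, p = 0.037). All 3 were in the E(spl) complex, so they are not independent sites, and this p does not measure an excess across the genome. The pair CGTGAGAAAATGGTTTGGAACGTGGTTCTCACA at 3R 26002613 to 26002645 lay in the intergenic peak of rank 1124 beyond E(spl)mgamma-HLH. Another, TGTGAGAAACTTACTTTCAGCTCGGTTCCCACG at 3R 26040016 to 26040048, lay in the E(spl)m8-HLH promoter peak of rank 2785. Both had a spacer of 17 bp and a peak in all 3 replicates.

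Without a preset motif, 1017 of 32896 8-mers were more frequent and 1159 less frequent within 100 bp of summits than in flanks (Fisher's exact test, adjusted p under 0.05). The 8-mers were not tested against positions of the same location class. Summit windows held 39.7% G and C and flanks 43.2%, so these counts are not free of differences in location and base composition. The lowest p belonged to TATCGATA and ATCGATAG, which overlap the DREF element, followed by CACTGAGA (3.34% against 0.404%) and CAACACTG (4.15% against 0.744%), all singled out after the values were seen. The first form of the Su(H) site by p was CGTGGGAA, at 0.991% of summits and 0.417% of flanks, 1020th of all 8-mers (Fisher's exact test, adjusted p = 0.0102). The other forms, TGTGGGAA, CGTGAGAA and TGTGAGAA, had ratios of 1.48, 1.72 and 1.43. They did not pass (Fisher's exact test, adjusted p from 0.253 to 0.406).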

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

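The tests of the Su(H) site below the threshold, of sites with 1 mismatch and of promoter peaks without a site were chosen after the results were seen. So were the tests of runs of adjacent genes, and of peaks outside promoters and sites in the E(spl) complex. The use made here of the ribosomal protein test was also chosen then, though that test was itself planned.

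The Su(H) site was also more frequent at summits in data that the comparisons left out, the pooled peaks below the threshold. Flanks were the only control for these ranks, and the pooled list includes background by design, so the excess does not show binding there. In the pooled peaks of rank 3834 to 7666, the Su(H) site was 1.51 times as frequent at summits as in flanks (3.34% against 2.22%, Fisher's exact test, p = 0.000473), and in the remaining ranks to 30000 it was 1.31 times as frequent (2.71% against 2.06%, Fisher's exact test, p = 2.03e-07). The promoter share was 49.3% in the first of these sets and 25.1% in the second.

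Most thresholded peaks were at promoters and lacked the Su(H) site. A first candidate explanation is signal over active promoters whatever the tagged factor: it requires ribosomal protein genes to be bound above chance, and they had 2.89 times the expected number of peaks, as this explanation needs. Sites 1 base away from the consensus could not account for most peaks, because allowing 1 mismatch raised the summit share over the flank share by only 3.22 percentage points (40.2% against 36.9%). The fusion protein may also have been at promoters without its own site, for instance through other proteins. Of the promoter peaks 96.6% had no site, which both this and a general promoter signal predict. The excess at ribosomal protein genes does not separate these explanations either, since both can place signal at active promoters. The lists were made with a control file, but neither that control nor an untagged library was analysed here, so these explanations cannot be told apart.

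The E(spl) complex held more peaks than genes of its lengths. Promoter signal alone predicts no excess of peaks outside promoters, whereas 4 members had one against 0.331 expected (permutation p = 0.00060), and 3.46% of runs of 12 adjacent genes elsewhere had as many. Neighbouring genes that share a peak would raise the total. The strongest peaks of the 8 members were 8 different ones, at ranks 76 to 3530, which argues against sharing as the source of their count. A share of 0.145 of the 6849 runs had 8 or more genes with a peak, so such totals also occur among adjacent genes elsewhere. Su(H) sites in the complex remain a candidate explanation. Of its 12 peaks 5 (41.7%) held a site, against 11.8% when these peaks were shifted within the complex (permutation p = 0.0094). Among the other 3821 peaks 3.45% held one. This explanation is a hypothesis, since open chromatin in the complex was not tested and the design has no group with altered Notch signalling.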

How the results depend on the processing

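Alternatives were planned, except the runs of adjacent genes and those for the replicates' own strongest peaks and the Su(H) site without the E(spl) complex, at promoters and outside promoters, and the class-matched controls of other motifs, which were chosen after seeing the data. Replicate agreement, promoter location and the Su(H) site ratio kept their direction and passed in every alternative run. The first could hardly fail, since the thresholded list was made from the same libraries. The site pairs numbered 3 or 4, and their test rests on 1 gene complex. Agreement in all 3 replicates ranged from 84.9% (50% reciprocal overlap) to 99.9% (1000 strongest peaks), the promoter share from 46.9% (200 bp) to 68.5% (1000 bp), and the site ratio from 1.33 (200 bp) to 2.38 (CGTGGGAA). No thresholded dm6 peak lay on unplaced contigs or chromosome Y, so leaving these out changed nothing.

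Mean rho was 0.646 and became 0.616 with 1 bp overlap, and 0.633 to 0.671 with a replicate left out. With the site sought within 200 bp, the rank difference was -73.0, in the other direction. Summits within 50 bp gave 355 more frequent and 213 less frequent 8-mers in place of 1017 and 1159. Passing lists numbered 8, but 5 within 1 kb of a start and 3 for the 1000 strongest peaks. The E(spl) complex lost its call there, with 5 and 3 members, on fewer counts, since the ratio to the expected count was 3.39 and 3.66 against 3.14. With 5 kb it had 12. Notch pathway components gained a call against shifted peaks, with 16, where the general placement of peaks at genes is lost too. Among the other lists, alternatives ended 10 calls and added 4, and leaving out a replicate changed none. For gene lists, that step only dropped thresholded peaks without a match in the remaining replicates. Nearly all peaks had such a match and the list still came from all replicates, so these calls could hardly change. The added calls were BMP, EGFR and cell cycle genes against shifts and neuroblast genes with 5 kb. Against class-matched positions Runx lost its call, and the ratios of Zelda (1.04) and the Pol III B box (0.5), neither of which passed, crossed 1.

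Some counts crossed the expected one. Of these lists only ecdysone genes had passed. Within 1 kb of a start this was so for Brd complex (0), dorsoventral (2), tracheal (3), gut (1), Hedgehog (2) and ecdysone genes (2). For the 1000 strongest peaks it was so for Brd complex (0), other Notch targets (3), mesoderm (4), gut (1), Hedgehog (1) and cell cycle genes (1), and with 5 kb for epidermis (8), germline (6) and Hedgehog genes (4). Against shifts it was so for other Notch targets (7), proneural (5), mesoderm (7), muscle (5), hemocyte (5), segment polarity (5), tracheal (3), epidermis (5), germline (2) and Wnt genes (6). Other Notch targets (7, 7.04 expected) also crossed without replicate 2 (7, 7.0 expected). The cause was not tested. Depth is unknown, so its limit on weak peaks could not be given.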

Other observations

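The counts of facing pairs, the class-matched controls of motifs other than the Su(H) site, the site ratios by location and the G and C shares were chosen after the values were seen. Facing pairs of Su(H) sites occur 15 times in the dm6 genome, 7 of them in the E(spl) complex. In the complex 3 of 7 lay within 200 bp of a thresholded summit, and outside it 0 of 8 (Fisher's exact test, p = 0.0769). A pair at the promoter of E(spl)mgamma-HLH (3R 25999557 to 25999589) lay under a pooled peak of rank 10385, and the pairs next to E(spl)m4-BFM and E(spl)m7-HLH lay under peaks in 2 and 3 replicate lists but under no pooled peak. The pair in a coding exon of CG43116 (3R 25996282 to 25996312) had neither a pooled peak nor a peak in any replicate list. Outside the complex, a pair in an intron of Cad74A (3L 17374659 to 17374688) had a pooled peak of rank 8642 and one in intergenic sequence 6537 bp from CG11726 a pooled peak of rank 28019, while pairs in introns of pyd, CG31176 and Gclc had no summit within 200 bp in any replicate list.

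Against random positions of the same location class, in place of flanks, Motif 1 was 6.11-fold, GAGA 1.92-fold and the Su(H) site 1.69-fold more frequent at summits, and the proneural E-box was 0.828-fold as frequent (Fisher's exact test, adjusted p = 0.0313). The Su(H) site ratio was 1.9 at promoter peaks and 1.4 at peaks outside promoters. Summit windows held 39.7% G and C, flanks 43.2% and class-matched positions 41.9%. The 500 strongest peaks were at 38.4%, and the 333 weakest at 40.8%. The dm3 lists gave 3570 thresholded peaks and the dm6 lists 3833.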
